A study of Mus musculus with 2 samples.

How the data were processed

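Total RNA of jejunum from male C57BL/6J mice was compared between a control diet and a high-glucose diet with 1 Affymetrix array per diet, per the labels. The mice were 4 weeks old at the start, acclimated for 2 weeks, and ate their diet for 4 weeks, to an age of 10 weeks. RNA came from a Trizol extraction, and 6 ug of it was turned into biotin-labelled cRNA, per the labels' protocols. How many animals contributed to each array is not given in the sources used here.

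The authors deposited 2 kinds of values. The first is a table of intensity values that the authors made before deposit with MAS5, Affymetrix's algorithm that summarises a probe set into 1 linear signal, per the submitters' processing notes, which give no version. It holds 22690 probe sets on each array. The scaling target is not given in the sources used here, and the values show that the arrays were not brought to a common level. The second is the authors' deposited table of their own comparison of the diets, which lists 1625 probe sets (7.16% of the array) with a gene symbol and a signal log ratio (SLR) on the log2 scale in steps of 0.1. Its direction, high-glucose against control, comes from the table's title. Its fold change column is the SLR turned into a signed fold and was not used further. The rule by which the authors selected these probe sets, and the scaling behind the SLR, are not given in the sources used here.

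Gene names came only from that comparison table, because no other pairing of probe sets with genes was used here. Of its probe sets, 42 carry no symbol. Among the other 1583, 1314 had a symbol current in the RefSeq annotation of GRCm38.p6, 213 were updated through a synonym listed there, and 56 kept the authors' symbol. The result is 1559 named genes. A gene of a list that is absent from the comparison table is unnamed here, which says nothing about whether it changed.

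For the signals, the value was the log2 ratio of high-glucose over control with no further scaling. Signals under a floor of 2.9, the mean of the arrays' 25th percentiles, were set to it. A ratio with 1 signal at the floor is a lower bound of the change, and none is given with both there. A probe set counted as expressed when its mean log2 signal was at or above the median of the 22626 probe sets that are not controls, which left 11315 probe sets and 1067 named genes. Each gene was represented by its brightest probe set. The design was fixed on the assumption that the deposited signals were comparable between arrays. As they were not, each ratio is reported mainly relative to the array-wide shift, the median log2 ratio of expressed probe sets, and is then called the relative log2 ratio. The uncorrected counts are kept beside it.

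With 1 array per diet no test of the diets is possible, and no p-value, standard error or count of significant genes is given. For 28 gene lists and 21 lists of cell type markers fixed before the data were examined, the median over the members was placed among 10000 random lists of the same size, matched on signal level in 20 bins. The random lists could draw the list's own members, which blunts the comparison for a large list that fills its bins. Medians were computed for lists with at least 4 members. A median under the 1st or over the 99th percentile is said to stand apart, as about 2 in 100 random lists do. The same was done with the SLR of the authors' deposited table over all listed members, with the matching again on the signals. Lists with fewer members were given as counts or left out.

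Genes were named by a rule fixed before the data were examined. It takes the 15 highest and 15 lowest expressed genes past 2-fold in the uncorrected ratio, without placeholder names or genes whose probe sets disagree in sign. It adds up to 4 expressed members per list with at least a 1.5-fold ratio, and a fixed set of 31 genes of lipid and sugar handling, of which 15 are named in the files and some are not reported here. The rule covers the signals. Genes named for their SLR in the authors' deposited table, list members beyond the rule, and the lists of liver-abundant and jejunal epithelium-abundant genes were chosen after values had been seen.

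The alternatives were 4 other scalings (median, 2% trimmed mean, quantile and loess), floors at the 10th and 40th percentile, no filter on low signals and a filter at the 75th percentile. The mean over a gene's probe sets, the exclusion of probe sets shared between transcripts (suffix x or s), thresholds of 1.5-fold and 3-fold, and the SLR in place of the signals were also tried. Counts over all probe sets, the alternatives for the SLR medians and random lists without matching were added after seeing the data.

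The procedure was tested on simulated data, in which a high-glucose array was drawn from the real control array with a shift of -1 and noise of 0.3 on the log2 scale. Of 50 genes simulated 1.5 lower on the log2 scale, 96% came out past 2-fold in the right direction, and their median was -1.52. Of 50 genes simulated 3 lower, 98% did, with a median of -2.91. All of those simulated 1.5 or 3 higher did (100%), with medians of 1.33 and 3.05, so the smaller increase was somewhat understated. None (0) of the 870 unchanged genes passed 2-fold, and 0 of 20 unchanged lists stood apart. The noise between real arrays of 1 group is unknown, so the simulation checks the computation and not the precision of the data.

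Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.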

Results

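Gene expression was measured in samples labelled as jejunum, the middle stretch of the small intestine, from male mice. The mice ate a regular AIN76 chow or a diet with 20% glucose for 4 weeks. For the signal arrays the tissue is known from the labels only, and their levels raise a doubt about it that is described below. The stated interest of the study was in genes of lipid metabolism. There was 1 array per diet, so every difference below compares 1 array with 1 other, has no replicate error, and cannot separate the diet from variation between animals or hybridisations. The number of arrays limits the precision. Values came from the authors' deposited table of their own comparison, which gives a signal log ratio (SLR, log2 scale, high-glucose against control) for 1625 probe sets, and from the signals of both arrays. An SLR of -1 is a 2-fold lower value on the high-glucose diet.

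These sources did not give the same picture. Over the 266 listed probe sets with a signal of at least 100 on both arrays, the SLR and the log2 ratio of the signals correlated with a Pearson r of 0.107 and a Spearman rho of 0.159. This correlation is across probe sets, which are not independent replicates. The signs matched for 167 of the 266 (62.8%). Each source is therefore described separately, and neither is a check on the other.

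In the authors' deposited table, genes that make fatty acids and cholesterol were listed lower on the high-glucose diet, as were circadian clock, interferon-response and B cell genes. Genes of fatty acid oxidation, ribosomal proteins, Paneth and goblet cell products and smooth muscle genes were mostly listed higher. The table holds 585 probe sets with an SLR above 0 and 1040 below 0, from -5.7 to 6.3. It lists small changes unevenly, since 206 probe sets lie between -0.4 and 0 but only 1 between 0 and 0.4. The authors' rule of selection is not given, and all listed probe sets have an SLR other than 0 on these samples, so the direction of a group in it is not independent evidence.

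All 8 listed genes of fatty acid synthesis and desaturation had a negative SLR in the authors' deposited table, with a median of -0.75 (percentile 0.205). When random lists were not matched on level, its percentile was 0.995, just under the limit of 1 for standing apart. They included Srebf1, the transcription factor that drives lipogenic genes, at -1.0, and fatty acid synthase (Fasn) at -0.9. The desaturases Scd2, Fads1 and Scd1 stood at -2.3, -0.9 and -0.6, and the glucose-responsive factor Mlxipl at -0.5. The 8 listed genes of cholesterol biosynthesis were also negative in the authors' deposited table, at a median of -0.55 that did not stand apart (percentile 7.79). Among them squalene epoxidase (Sqle) had an SLR of -0.8 and Fdps -0.7 in the authors' deposited table. The 4 listed genes of triacylglycerol synthesis and lipid droplets were negative as well, at a median of -0.7 that did not stand apart (percentile 7.6). Of these, Dgat2, which adds the last acyl chain, stood at -1.2 in the authors' deposited table and Mogat2, the enterocyte monoacylglycerol acyltransferase, at -0.3.

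Mitochondrial fatty acid oxidation and ketogenesis went the other way in the authors' deposited table, with 7 of 8 genes positive and a median SLR of 0.6 (percentile 96.5, not apart). Among these were the thiolase Acaa2 at 0.8 and the carnitine-acylcarnitine carrier Slc25a20 at 0.7. The exception was Ppara, a transcription factor that activates this pathway, at -0.7. Of the chylomicron and apolipoprotein genes, Apoa1 and Apob each had an SLR of 0.7 in the authors' deposited table and Apoc2 -0.3. All 6 listed genes of sugar digestion and transport were negative there (median -0.6, percentile 9), among them the fructose transporter Slc2a5 at -0.8, the glucose transporter Slc2a2 at -0.6 and the sodium-glucose cotransporter Slc5a1 at -0.3. The gluconeogenic enzyme Pck1 stood at -2.1 in the authors' deposited table.

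The circadian clock genes formed 1 of the 4 lists that stood apart among the 32 tested on the authors' deposited table. Random lists of independently drawn genes would give 0.64. Genes of a list can vary together between any 2 arrays, and some lists share genes, so 0.64 does not measure chance between animals. All 8 were negative, with a median SLR of -1.15 (percentile 0.01). Per1 and Per3 of the period family stood at -2.6 and -2.0 in the authors' deposited table, and the clock output genes Dbp and Tef at -2.2 and -1.3. Of 13 interferon-response genes, 12 were negative, with a median SLR of -1.0 that no random list went below (percentile 0). Ifi44, Stat2, Ifit3 and Usp18 had values of -1.5, -1.3, -1.2 and -1.2 in the authors' deposited table, while Tap1, a peptide transporter of antigen presentation, was listed at 3.9.

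B cell genes had the lowest list median in the authors' deposited table, an SLR of -2.1 with 11 of 12 genes negative (percentile 0.005). The B cell receptor regulator Cd22 stood at -5.5, the immunoglobulin heavy chain gene Ighm at -4.0, and Cr2 and Ms4a1 at -3.7 each. The kappa light chain gene Igkc was listed at 0.5 in the authors' deposited table. All 11 listed genes of proliferating cells were negative (median -0.5, percentile 12.5).

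Several groups in the authors' deposited table were positive throughout but did not stand apart among level-matched lists. All 30 ribosomal protein genes had a positive SLR with a median of 0.5. Their matched random lists could draw these same genes and mostly had medians between 0.45 and 0.5. That comparison therefore says little about the ribosomal list. All 7 Paneth cell genes were positive (median 0.9), with lysozyme (Lyz1) at 1.0 and Mmp7 at 0.8, and all 5 goblet cell genes (median 0.6), with Spink4 at 0.9 and Guca2a at 0.8. All 10 smooth muscle genes were positive (median 1.0), with Tagln at 1.3 and Actg2 at 1.1. When random lists were not matched on level, the smooth muscle list stood apart (percentile 99.5) and the ribosomal list did not (98.4). Leaving out placeholder names, the 15 highest genes of the authors' deposited table were led by Tram2 at 5.6 and included Bco1, which cleaves beta-carotene, at 4.8. Bco1 was the only one of those 15 that counted as expressed on the signal arrays.

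**Figure D1:**
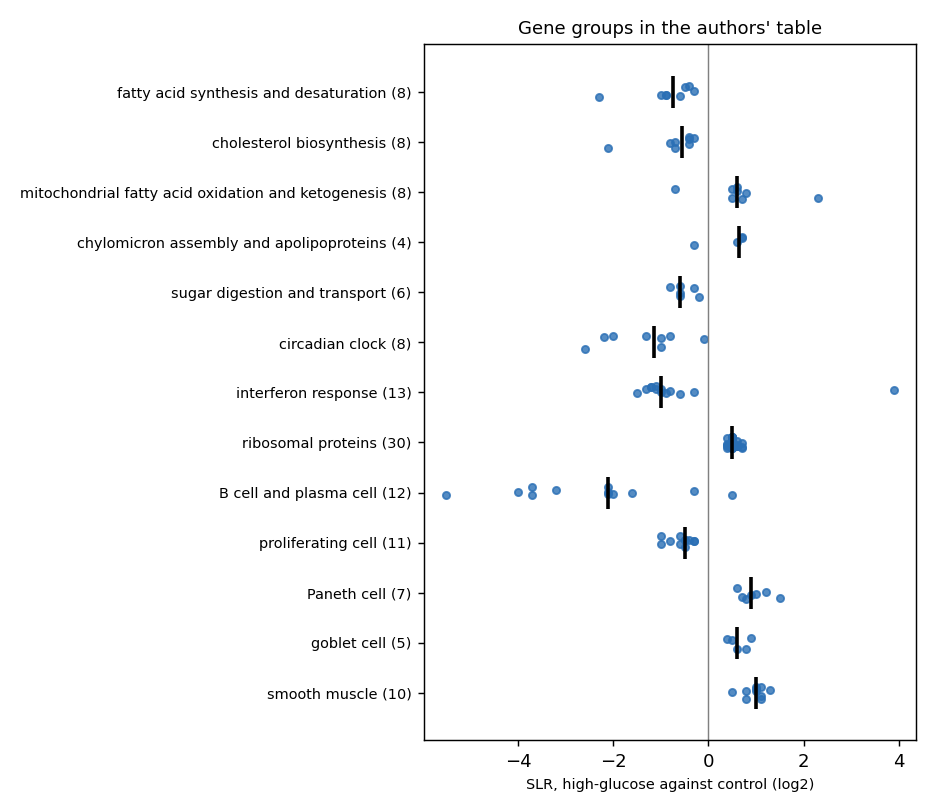
SLR of the authors' deposited table (horizontal axis, log2, high-glucose against control) for members of 13 gene lists, 1 point per gene, with the number of listed genes in brackets and the list median as a bar. The 8 circadian clock genes and the 8 fatty acid synthesis genes all lie below 0, and the 30 ribosomal protein genes all lie above 0.

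In the deposited signals, the high-glucose array was lower almost throughout, and beyond that shift the clearest groups were pancreatic acinar genes and enzymes of cholesterol and fatty acid synthesis, all lower on the high-glucose array. The median signal over all probe sets was 13.1 on the control array and 7.9 on the high-glucose array, and the median log2 ratio of expressed probe sets was -0.97, a 1.96-fold lower level. Relative log2 ratios below are measured from that shift.

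Of 1067 expressed named genes, 3 were at least 2-fold higher and 507 at least 2-fold lower on the high-glucose array as deposited. Relative to the shift, 41 were higher and 57 lower. Over all 11315 expressed probe sets, named or not, 557 were higher and 562 lower relative to the shift. Probe sets in the authors' comparison table passed the relative 2-fold mark about as often as others, 103 of 1110 (9.28%) against 1016 of 10205 (9.96%). Of 23 lists with enough expressed members, 6 stood apart. Random lists of independently drawn genes would give 0.46, which likewise does not measure chance between animals.

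The 7 expressed genes of cholesterol biosynthesis were all at least 1.5-fold lower relative to the shift, with a median relative log2 ratio of -1.84, a 3.59-fold lower level that no random list went below (percentile 0). Farnesyl diphosphate synthase (Fdps) had a signal of 522.5 on the control array and 48.8 on the high-glucose array, a relative log2 ratio of -2.45. Msmo1 and Sqle followed at -2.35 and -2.25, and Hmgcs1, an early enzyme of the pathway, at -1.84. Fatty acid synthesis had a median of -0.63 over 7 genes (percentile 0.085), of which 4 were at least 1.5-fold lower. ATP citrate lyase (Acly), which supplies acetyl-CoA to both pathways, had a relative log2 ratio of -1.34, Fasn -1.18, Mlxipl -0.71 and Fads1 -0.63. Srebf1 and Scd1 lay nearer the shift, at -0.37 and -0.16, and Dgat2 stood at -0.43.

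Genes of mitochondrial fatty acid oxidation had a median relative log2 ratio of 0.34 (percentile 97.8, not apart), with Hadhb at 0.79, Slc25a20 at 0.64, Ppara at -0.03 and Acaa2 at -0.35. As deposited, all 8 of these genes had a lower signal on the high-glucose array, so their sign depends on the shift. The intestinal fatty acid binding protein Fabp2 was higher on either scale, with signals of 455.3 and 557.9 and a relative log2 ratio of 1.26. Apob stood at 0.14. Among sugar transporters Slc2a2 stood at -0.51 and Slc2a5 at 0.85, the latter from signals of 13.3 and 12.2. Slc5a1 and Mogat2, with signals of 4.6 and 2.2 on the control array and 0.8 on the high-glucose array, did not count as expressed.

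All 6 expressed genes of pancreatic acinar cells were lower on the high-glucose array, with a median relative log2 ratio of -4.26, a 19.2-fold lower level (percentile 0). The signal of the protease gene Cela3b was 1725.7 on the control array and 31.2 on the high-glucose array. The corresponding signals were 1345.8 and 39.3 for trypsin 4 (Try4), 261.3 and 4.7 for colipase (Clps), 418.3 and 12.6 for Rnase1, 514.3 and 16.7 for Zg16, and 223.8 and 5.4 for Reg1. Zg16 also belongs to the goblet cell list and Reg1 to the epithelial antimicrobial list. Outside the list, Dmbt1 was lower at -3.61, and Klk1 and Pnliprp2 were at least 12.6-fold and 7.23-fold lower relative to the shift, since their high-glucose signals lay under the floor.

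Epithelial antimicrobial and immune factors had a median of -1.25 over 4 genes (percentile 0.4). That value rests on Reg1 at -4.40 and the acute-phase gene Saa1 at -2.18, with Cxcl9 at -0.32 and Il18 at 0.11. Xenobiotic metabolism had a median of -0.38 over 9 genes (percentile 0.375), with the cytochromes Cyp2c55 and Cyp2b10 at -1.64 and -1.56 and, in the other direction, Gstp1 at 1.37. Its percentile was 1.04 under quantile normalization, which no longer stood apart. Peptide and amino acid digestion and transport had a median of 0.98 over 5 genes (percentile 99.4), with Mep1a at 1.86, Ace at 1.14 and Slc7a8 at 0.98, these 3 with signals under 20. The other members, Slc3a2 and Anpep, lay below the shift at -0.20 and -0.06. It did not stand apart with a floor at the 40th percentile (0.49), without a filter (0.59) or after loess centring (0.77).

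The 3 genes past 2-fold higher as deposited were Ssty1, a multicopy Y-linked gene, Usp2 and Rpf2, at relative log2 ratios of 3.33, 2.43 and 2.06. The Ssty1 signals were 5.3 and 27.2. Among genes past 2-fold lower, Nabp2 was at least 5.57-fold lower relative to the shift, and Cpeb4 stood at -2.02. The named probe set of beta-actin (Actb) was higher at 1.79, with signals of 418.6 and 736.1, whereas the array's 3 control probe sets of Actb lay close to the shift, at 0.13 (3' end), -0.01 (middle) and -0.16 (5' end). As deposited, the control probe sets were lower and the named one higher on the high-glucose array.

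Lists that stood apart by SLR did not all do so by signal. The circadian clock list had a median relative log2 ratio of 0.05 over 6 genes (percentile 62.0), with Dbp at 0.71 and Per1 at 0.42 but Bhlhe40 at -0.76 and Per3 at -0.57. Interferon-response genes had a median of 0.21 over 12 genes (percentile 95.4), with Usp18 at 1.42, Oas1a at 1.37, Psmb9 at -0.23 and Stat2 at -0.36. B cell genes mostly did not count as expressed, with signals of 0.3 on both arrays for Cd22 and 0.2 on both for Ighm. Ribosomal protein genes had a median of 0.25 over 30 genes (percentile 68.6, among random lists that could draw these same genes), and their median uncorrected log2 ratio was -0.72.

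**Figure D2:**
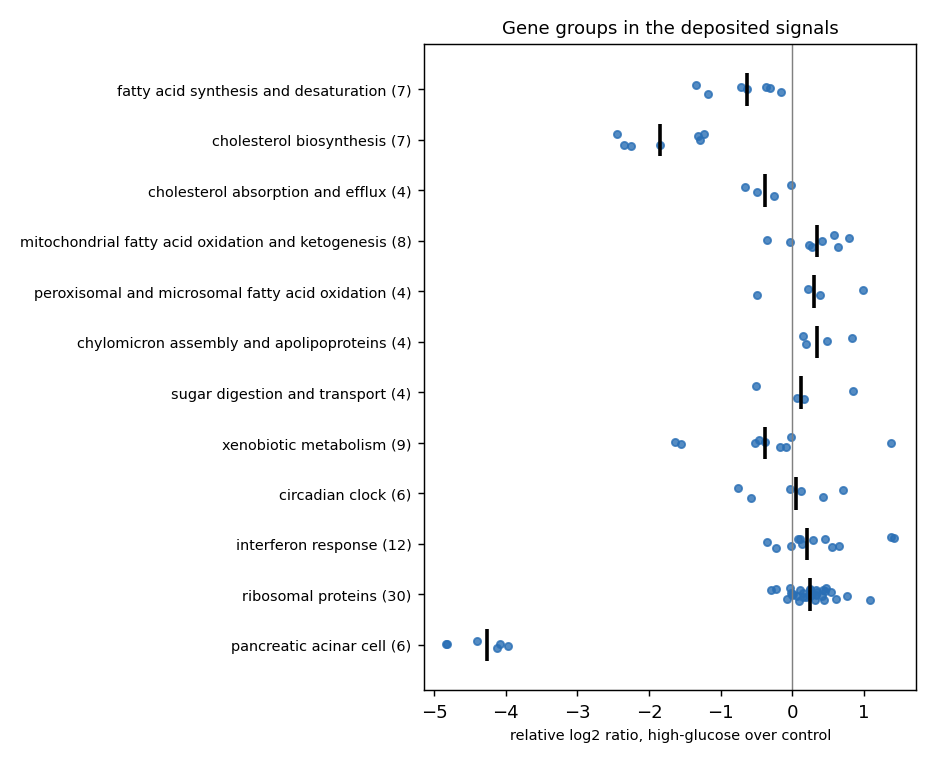
Relative log2 ratio of the deposited signals (horizontal axis, high-glucose over control, measured from the median of expressed probe sets) for expressed members of 12 lists, 1 point per gene, with the number of genes in brackets and the median as a bar. The 6 acinar genes lie between -4.83 and -3.97 and the 7 cholesterol biosynthesis genes all lie below -1.

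Signals were also looked at for genes known for abundant expression in a tissue. All 14 named genes of a liver-abundant list counted as expressed, among them plasminogen (Plg) with signals of 3968 and 1994 and the protease inhibitor Serpina1a with 5069 and 4065 on the control and high-glucose arrays. Of 28 named genes of a jejunal epithelium-abundant list, 10 counted as expressed, among them Fabp2. Counting as expressed is a low bar. Of the liver list, 13 of 14 genes lay above the 90th percentile of the array on both arrays and 0 below its median. Of the jejunal list, 2 and 1 of 28 lay above the 90th percentile on the control and high-glucose arrays, and 20 and 16 below the median. Lyz1 had signals of 5.4 and 4.6, Guca2a 0.7 and 0.4, and the smooth muscle gene Actg2 4.5 and 5.3. Of the marker lists fixed before the data were examined, 7 of 8 enterocyte genes, 3 of 5 goblet cell genes and 2 of 7 Paneth cell genes counted as expressed. These 2 Paneth cell genes were Habp2, which is also on the liver-abundant list, and Pnliprp2, which fell with the acinar genes. Lyz1, Mmp7, Itln1, Defa5 and Defa29 did not count as expressed. Above the 90th percentile lay 2 of the 8 enterocyte genes on each array, 1 and 0 of the goblet cell genes on the control and high-glucose arrays, and 0 of the Paneth cell genes. Probe sets differ in affinity, so these signals do not rank the genes by abundance.

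**Figure D3:**
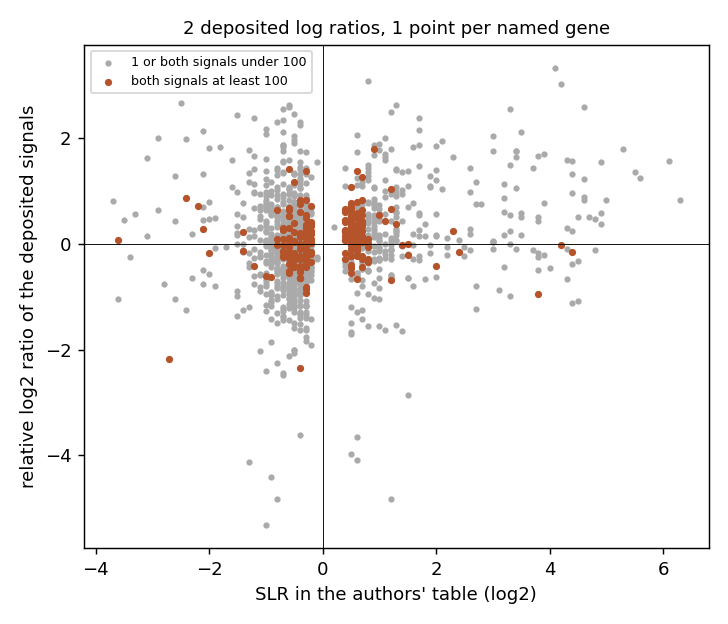
Relative log2 ratio of the deposited signals (vertical axis) against the SLR of the authors' deposited table (horizontal axis, log2), 1 point per named gene for the 1458 genes with a ratio, and in colour the 250 with both signals at least 100. The points show no clear diagonal, and few listed genes have a positive SLR under 0.4.

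Control probe sets described the hybridisations. The 18 probe sets of hybridisation spikes, RNAs added just before hybridisation, had a median log2 ratio of 0.12 with an interquartile range of 0.26. The 24 probe sets of poly-A spikes, the bacterial RNAs that can be added before labelling, had a median of -0.93 with an interquartile range of 0.34. The 3' to 5' signal ratio of Actb was 2.33 on the control array and 2.87 on the high-glucose array, and that of Gapdh 0.706 and 0.773. The 18S ribosomal RNA probe sets had signals of 843 and 1706 at the 3' end, 515.2 and 1488 in the middle and 6495 and 5229 at the 5' end on the control and high-glucose arrays. Within an array, the only repeat measurement was another probe set of the same gene. Over 21 genes with a pair of expressed probe sets the relative log2 ratios correlated with a Pearson r of 0.34 and a Spearman rho of 0.53 across genes, 15 matched in sign, and the SD of the difference was 0.48. In the authors' deposited table, the SLR of 22 genes with a pair of listed probe sets correlated with a Spearman rho of 0.82 across genes, and 21 matched in sign, though both members of each pair had been selected for that table. None (0) of the 21 pairs of signal ratios had its brighter probe set past 2-fold relative to the shift. Of the larger changes, that of Actb could be set against its control probe sets, which did not show it.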

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

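The counts of expressed named genes past 2-fold, 3 higher and 507 lower as deposited, depended on how the arrays were scaled. They became 25 higher and 100 lower after median scaling, 45 and 53 after trimmed mean scaling, 44 and 61 after quantile normalization, and 39 and 64 after loess centring. Without a filter 30 genes were higher and 645 lower, and with the filter at the 75th percentile 1 was higher and 298 lower. At 1.5-fold the counts were 9 and 825, and at 3-fold 1 and 132. Over all probe sets, a count added after seeing the data, they were 41 and 5402. By the SLR of the authors' table they were 271 and 157 over all listed genes, expressed or not, and 69 and 89 over those that counted as expressed, a count added after seeing the data.

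Relative to the shift, list medians mostly moved little under the other settings of the signals. Among 218 recomputed medians of 23 lists, 217 moved from the main value by less than the spread of random lists and 6 changed sign, none of them a list that stood apart. That spread is the distance from the middle to either end of the range that held most random list medians. The median of cholesterol biosynthesis ranged from -1.84 to -1.70, of fatty acid synthesis from -0.63 to -0.47, of acinar genes from -4.39 to -4.08 and of epithelial antimicrobial factors from -1.36 to -1.22. No setting left out Reg1 or Saa1, on which the median of the epithelial antimicrobial list rests. Less stable were xenobiotic metabolism, from -0.49 to -0.14, and peptide and amino acid digestion and transport, from 0.49 to 0.98. The first no longer stood apart under quantile normalization, and the second with the higher floor, without a filter or after loess centring. Of 1763 recomputed ratios of 186 single genes, to which list members were added after seeing the data, 76 changed sign, none for a gene past 2-fold relative to the shift. The 75 recomputed medians of the SLR, added after seeing the data, all moved by no more than that spread.

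Replacing the signals by the SLR of the authors' table changed more. The median turned to -0.6 for peptide and amino acid transport and to 0.4 for xenobiotic metabolism. Of lists that had not stood apart by signal, it also changed sign and moved by more than that spread for circadian clock (0.05 to -1.15), interferon response (0.21 to -1.0), oxidative phosphorylation (0.18 to -0.2), genes of common reference use (0.11 to -0.35) and sugar digestion and transport (0.12 to -0.6). It moved without a change of sign to 0.5 for ribosomal proteins, -0.55 for cholesterol biosynthesis, -0.4 for epithelial antimicrobial factors and -0.15 for acinar genes. Of 98 expressed named genes past 2-fold relative to the shift, 36 had an SLR of the opposite sign. Among those chosen by the naming rule or belonging to a list, these were Ace (-0.7), Gstp1 (-0.3), Oas1a (-1.0), Usp18 (-1.2), Acta2 (1.0), Cd24a (0.6), Clps (1.2), Cyp2b10 (0.8), Cyp2c55 (1.4), Klk1 (0.6), Pnliprp2 (1.5), Rnase1 (0.6), Zg16 (0.5) and Usp2 (-1.5). The scaling alternatives change the counts by construction, since they remove most or all of the array-wide shift (a shift of -0.25 remained after median scaling). For the other differences the cause was not tested. With 1 array per diet no array could be left out. No paired analysis was possible because each group has 1 array. Low signals limit several marker lists, as 1 of 11 proliferating cell, 2 of 12 B cell, 2 of 7 Paneth cell and 3 of 10 smooth muscle genes counted as expressed.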

Other observations

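All tests in this part were chosen after the results they bear on, or values close to them, had been seen.

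Further genes had large ratios in the comparison table that their signals did not show. Plg, Cyp2c38, Akr1c20 and Scarb1 had an SLR of 4.2, 4.4, 3.8 and 3.8 in the authors' deposited table. The signals of Plg were 3968 and 1994, those of Cyp2c38 235.8 and 108.0, those of Akr1c20 570.7 and 150.3, and those of Scarb1 215.2 and 77.7. Bbox1, the last enzyme of carnitine synthesis, had an SLR of -3.6 in the authors' deposited table and signals of 665.6 and 356.9. The ileal bile acid binding protein Fabp6 had an SLR of -2.1 in the authors' deposited table and signals of 1.2 and 0.8, under the floor on both arrays, so it has no signal ratio to compare.

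For the first pattern, the mismatch between the comparison table and the signals, noise of low signals and a turned direction are both argued against by a Pearson r of 0.107 among probe sets with signals of at least 100, and misplaced rows by control signals of different probe sets of 1 gene, which correlated with a Spearman rho of 0.801 over 22 genes. Whether the deposited signals were measured in another tissue, such as liver, stays open and is a hypothesis only, since the labels name jejunum for both samples. The median percentile of liver-abundant genes lay at least 59.6 points above that of jejunal epithelium-abundant genes on each array. This sets signals of different probe sets against each other, over lists written after many of the values had been seen (14 of 84 and 28 of 74 genes named). It shows high signals of liver-abundant genes and mostly low ones of jejunal genes on both arrays, but does not settle which tissue was measured. With the same limit, the median percentile on the control and high-glucose arrays was 99.4 and 99.2 for 5 liver genes not looked at beforehand (C3, Dio1, Mbl2, Pzp and Tdo2), 46.5 and 50.3 for the 4 epithelial marker lists fixed before the data were examined, when pooled, and 27.1 and 36.2 for smooth muscle. Of the pooled lists, the enterocyte list lay at 60.9 and 60.3, goblet cell at 75.1 and 68.5, Paneth cell at 31.4 and 21.4 and enteroendocrine at 34.0 and 38.0. Some liver list genes, such as Apob, Saa1 and C3, are also expressed in intestine. In turn, Habp2 of the Paneth cell list is also on the liver-abundant list. Zg16, with the highest control signal of the goblet cell genes (514.3), is also on the acinar list. No biological explanation was tested.

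The second pattern is the lower signal over the whole high-glucose array. Less messenger RNA per total RNA in the tissue is argued against by the poly-A spikes, whose median log2 ratio of -0.93 lies close to the shift of -0.97 although they do not come from the tissue, provided they were added in equal amount to both samples, which was not tested and stays open. On the other side, the 18S ribosomal RNA probe sets lay above the shift, at relative log2 ratios of 1.99 (3' end), 2.5 (middle) and 0.66 (5' end). Less labelled target on the high-glucose array, left unscaled, may account for it, since the hybridisation spikes, added later, had a median of 0.12.

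The third pattern is the lower level of acinar transcripts on the high-glucose array. Pancreatic tissue in the control sample may account for it, as all 6 genes were lower by a like amount, with an SD of 0.377 on the log2 scale. A joint change of these genes for another reason would also give a like amount, so this cannot tell the explanations apart. In the authors' deposited table, 3 of the 6 had a positive SLR and 3 a negative one, with a median of -0.15. Zg16 and Reg1 are also expressed in intestine, whereas Cela3b, Try4 and Clps are abundant pancreatic transcripts, with control signals of 1725.7, 1345.8 and 261.3. A response to the diet stays open and was not tested, since there is 1 array per diet.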
